A study of Mus musculus with 24 samples.

How the data were processed

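Male C57BL/6J mice of 9 to 10 weeks were fasted for 10 h and injected intraperitoneally with 350.0 mg/kg acetaminophen in PBS. They were killed after 12, 24, 36, 48 or 72 h (4 animals each), and 4 untreated animals served as 0 h. Whether the untreated animals were fasted, and the hours of dosing and killing, are not stated by the labels. RNA of 30 to 50 mg of the caudate lobe was made into stranded mRNA libraries (TruSeq) and sequenced on a NextSeq 500 with paired reads of 36 cycles.

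Per the submitters' processing notes, reads were checked with FastQC 0.10.1, aligned to GRCm38 with TopHat2 2.1.0 and Bowtie2 2.2.6.0, counted per gene with HTSeq 0.5.4p3 and analysed with DESeq2 in R 3.4.2. The annotation release, the strand setting and the rule for reads that map to several places are not stated. The deposited signal values are read counts that the authors normalised by dividing by 1 size factor per library: each value was a whole multiple of the smallest value of its library (100% of values within a tolerance of 0.01 reads). The authors' tables also hold the log2 ratio of each time point over 0 h from their model, as deposited. The authors' p-value and adjusted p-value columns, as deposited, come from the same model and were used only to compare calls.

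The table had 39756 rows with 39179 Ensembl identifiers, and 324 identifiers stood on several rows and were kept once. Symbols came from the table for 22922 genes and from GENCODE vM21 for 14850, and 1407 genes had none. 96 symbols belonged to several identifiers. Coordinates are those of GRCm38 in the same annotation. Libraries were grouped by the labels. Depth was taken as the sum of recovered reads, 5.61 to 17.2 M per library, and intervals and floors cover counting error only. A gene with 0 reads in all libraries of a group was given a floor of 3 reads per library.

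The tests of genes and libraries, the gene lists, the thresholds and the alternatives were chosen before the data were examined, except where a choice is said to have been made later. The plan named edgeR on counts, with limma on log2 values if the files held no counts. Since the deposited values were counts divided by size factors, the limma branch was used, and edgeR, voom and DESeq2 on the recovered reads were run as alternatives. limma-trend 3.58.1 in R 4.3.3 was fitted to log2(value + 1) of 17777 genes with a mean of at least 1 over all 24 libraries, with 6 group means. Each time was compared with untreated and with the time before it, and p was adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. Fold changes are on this log2 scale, with the standard error (SE) of the model, and means ± SD are normalised read counts. Comparisons with untreated share the same 4 untreated libraries.

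The 34 gene lists (5 to 26 genes) were tested with camera of limma on the same log2 values, not on log2 CPM as first planned (changed after the values were seen to be normalised), with a preset correlation between genes of 0.01, and list p are from this test unless stated. p was adjusted over 170 tests of a list at a time against untreated, and separately over 136 tests of consecutive times. Beside it stood camera with an estimated correlation, fry, and the number of genes adjusted over the list alone. The lists were marker genes of liver zones and cell types and genes of stress, inflammatory, metabolic, cell cycle and clock programmes. Library shares and totals were compared by two-sided exact permutation tests of 4 against 4 animals (70 arrangements, smallest p = 0.0286). Principal components used the 500 most variable genes.

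Genes were named by rule. For a time against untreated these were the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among those past the threshold. A mean of at least 5 in the higher group, no overlap between the groups and a symbol that was not a predicted or clone name were required (Gm, Rik, AC, BC, AI and pseudogenes, with AU, AW, LOC and CT added after the names were seen). For consecutive times 5 per direction were taken, and any list member may be named. Some genes that met the rule are not reported here. Genes with near-identical copies (Hspa1a and Hspa1b, Gsta1 and Gsta2, Saa1 and Saa2, Mup, Cyp2a, Cyp4a12, Cyp2c, Sprr2 and haemoglobin genes) are marked uncertain.

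Alternatives were edgeR 4.0.16 (quasi-likelihood, relative log expression factors), limma-voom, DESeq2 1.42.0, scaling by total reads, no filter, a filter of 1 CPM in 4 libraries, pseudocounts of 0.5 and 5, only the 8 libraries compared, a replicate block, leaving out each library, and leaving out the low-numbered animals. edgeR with TMM (meant where edgeR is named without factors), TMM factors in limma, and leaving out the 3 libraries under 10 M reads were added after the data were seen. Simulated data of 17753 genes had 200 changed at 24 h. The test called 14% of log2 changes of 0.5, 66% of 1 and 100% of 2 or 3. 8 of 148 calls were false (5.41%). 1 of 20 unchanged lists had an unadjusted p under 0.05, and 20 of 20 changed lists were called. Recovery by read count and the list test in real livers were not examined. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.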

Results

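Liver mRNA (caudate lobe) of male C57BL/6J mice was sequenced in 24 libraries that fell into 6 groups of 4 animals. One group was untreated, and the others were killed 12, 24, 36, 48 or 72 h after an intraperitoneal dose of 350.0 mg/kg acetaminophen, an analgesic that kills hepatocytes in overdose. The libraries held 5.61 to 17.2 M (mega) reads assigned to genes, and 16509 to 19560 genes had at least 1 read in a library. Untreated libraries held 10.8 to 11.9 M reads, and those of 24 h 14.9 to 16.2 M (exact permutation p = 0.0286 against untreated). The ranges were 5.61 to 16.3 M at 12 h, 7.92 to 17.2 M at 36 h, 10.4 to 15.9 M at 48 h and 12.2 to 15.8 M at 72 h (exact permutation p = 0.629, 0.514, 0.143 and 0.0286). Of 24 mitochondrially encoded genes 14 had reads (read loss in processing untested). Their transcripts took 0.0364% ± 0.00678 (SD, n = 4) of the reads in untreated livers and 0.0576% ± 0.0102 at 72 h (exact permutation p = 0.0286, the minimum). The share was 0.0761% ± 0.0299 at 12 h, 0.0431% at 24 h, 0.0376% at 36 h and 0.0337% at 48 h (exact permutation p = 0.0857, 0.400, 0.800 and 0.743). Animals of 12 h (numbers 1 to 4) and 36 h (6 to 9) carried numbers of another series than the untreated, 24, 48 and 72 h animals (1149 to 1172). No untreated animal belonged to the low series, so series and group cannot be told apart at 12 and 36 h.

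**Figure D1:**
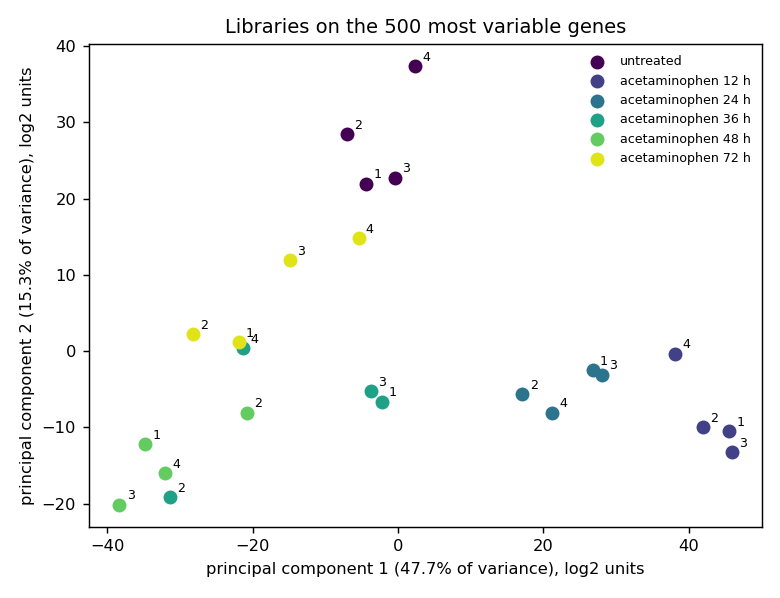
Scores of the 24 libraries on the first and second principal components of the 500 most variable genes (47.7% and 15.3% of the variance, log2 units); each point is 1 animal, coloured by group. The 12 h livers lie at one end of component 1 (38.1 to 45.9) and the 48 h livers at the other (-38.3 to -20.8), and the 36 h livers spread from -31.3 to -2.27.

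Each time point was compared with the untreated group to show which transcripts differed at that time after the dose. At an adjusted p under 0.05, 5776 of 17777 genes differed at 12 h (2923 higher, 2853 lower), 3376 at 24 h (1595 and 1781), 2242 at 36 h (1221 and 1021), 4095 at 48 h (2374 and 1721) and 283 at 72 h (170 and 113). The authors' own tables listed 5707, 3659, 2605, 4243 and 632 genes at an adjusted p under 0.05 for the 5 times. Of the genes called here 93.7%, 95.7%, 93.5%, 94.5% and 91.2% were among them, all with the same direction. Scaling by total reads in place of the deposited size factors shifted the median of all genes by 0.189 (log2) at 24 h, 0.128 at 36 h and 0.146 at 48 h. Under that scaling the split became 3065 higher and 991 lower at 24 h, 1763 and 528 at 36 h, and 3137 and 790 at 48 h. Changes are given relative to the deposited scaling. Of 34 gene lists, camera with a preset correlation called 22 at 12 h (11 higher, 11 lower), 24 at 24 h (11 and 13), 17 at 36 h (9 and 8), 19 at 48 h (10 and 9) and 16 at 72 h (9 and 7). With an estimated correlation it called 0 at all 5 times (smallest adjusted p = 0.0891), with 9, 9, 8, 8 and 5 at an unadjusted p under 0.05, and fry called 21, 19, 14, 15 and 7.

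**Figure D2:**
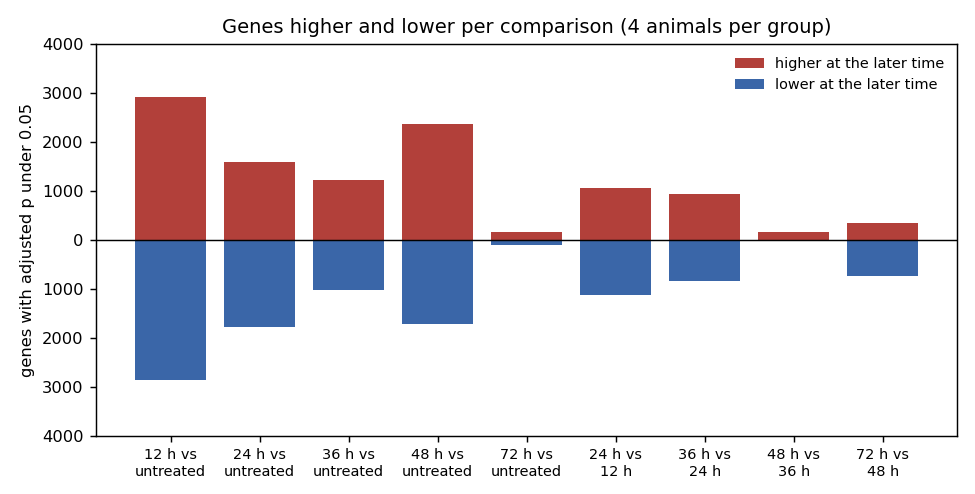
Number of genes with adjusted p under 0.05 in each comparison (y axis), higher drawn upward and lower drawn downward, for the 5 times against untreated and the 4 consecutive pairs of times (x axis). The count falls from 5776 at 12 h to 2242 at 36 h, is 4095 at 48 h and is 283 at 72 h.

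At 12 h the livers carried high levels of stress-response transcripts. Atf3, a stress-induced transcription factor (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039 on GRCm38), rose from 58.7 ± 35.6 to 6344 ± 677, log2 fold change 6.94 with SE 0.38, adjusted p = 7.72e-12 (normalised read counts, mean ± SD, n = 4). Hspa1a, an inducible Hsp70 chaperone, rose from 7.02 ± 4.54 to 2332 ± 1686, log2 fold change 8.09 with SE 0.63, adjusted p = 2.50e-09, with its reads uncertain against the near-identical Hspa1b (87.6 ± 31.4 to 6430.1 ± 3335, adjusted p = 7.02e-09). The cystine transporter Slc7a11 rose from 2.34 ± 2.38 to 207 ± 28.4, log2 fold change 6.26 with SE 0.56, adjusted p = 1.40e-08. Slc1a2, a glutamate transporter of hepatocytes around the central vein (ENSMUSG00000005089, chromosome 2, 102658659 to 102790784), fell from 2161 ± 651 to 114 ± 79.5, log2 fold change -4.47 with SE 0.49, adjusted p = 3.00e-07.

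Of 16 heat shock response genes 15 rose, and 15 when adjusted over the list alone (adjusted p = 6.08e-17, adjusted p = 0.0891 with an estimated correlation). They included Dnajb1 (3.82), Hsp90aa1 (3.21), Hspb1 (4.25) and Bag3 (2.75), given as log2 fold changes. Among 18 immediate early genes, the first transcription factors to respond to a stimulus, 14 rose and 17 did so adjusted over the list alone (adjusted p = 4.05e-11, adjusted p = 0.0891 with an estimated correlation). Examples were Klf6 (3.66), Maff (4.02), Jun (3.43) and Fosl1 (5.26). The 21 targets of NRF2, the regulator of the oxidative stress response, held 14 that rose and 2 that fell (14 and 3 adjusted over the list alone; adjusted p = 2.83e-07, adjusted p = 0.141 with an estimated correlation). Srxn1 (773 ± 72.3 to 17915 ± 3479.8, log2 fold change 4.52), Hmox1 (2.86) and Gclc (2.36), which makes glutathione, rose, and Abcc3 (-0.56) and Taldo1 (-0.40) fell. Within the unfolded protein response 12 of 20 genes rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 1.56e-07, adjusted p = 0.178 with an estimated correlation). Examples were Ddit3 (4.42), Ppp1r15a (2.46) and the chaperone Hspa5 (1.91), while Herpud1 (-0.75) fell. Of 21 p53 targets 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0187, adjusted p = 0.357 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 153 ± 78.8 to 2225 ± 792 (log2 fold change 3.96), and Gdf15 (2.17) and Mdm2 (0.86) rose too.

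Transcripts of lipid synthesis were low at 12 h. All 23 cholesterol synthesis genes fell, over all genes and adjusted over the list alone (median log2 fold change -2.11, adjusted p = 8.06e-17, and adjusted p = 0.155 with an estimated correlation). They included Idi1, an isomerase of the isoprenoid pathway (30.6 ± 8.49 to 3.14 ± 2.38, log2 fold change -3.19), and Nsdhl (-3.05). Among 19 fatty acid synthesis genes 15 fell, and 15 adjusted over the list alone (adjusted p = 4.77e-09, adjusted p = 0.161 with an estimated correlation). Examples were Srebf1 (-2.61), Thrsp (-3.88), Scd1 (-2.49) and Fasn (-2.36). The 25 fatty acid oxidation genes split into 6 that rose, such as Acot2 (3.35), Pdk4 (3.02) and Cyp4a14 (3.55), and 4 that fell, such as Fabp1 (-1.58) and Cpt1a (-0.62) (7 and 4 adjusted over the list alone; adjusted p = 0.435, adjusted p = 0.879 with an estimated correlation). Of 13 gluconeogenesis genes 3 fell, namely Pck1 (-1.44), G6pc (-1.75) and Fbp1 (-0.60) (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.162, adjusted p = 0.612 with an estimated correlation). For bile acid synthesis and transport 15 of 18 genes fell, and 16 adjusted over the list alone (adjusted p = 3.68e-08, adjusted p = 0.155 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 2059 ± 719 to 179.6 ± 102 (log2 fold change -3.69), and the canalicular export pump Abcb11 from 6381 ± 568 to 1571 ± 326 (log2 fold change -2.04).

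Genes of the pericentral zone, where acetaminophen is bioactivated, were low as well: 18 of 25 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 5.12e-10, adjusted p = 0.124 with an estimated correlation). Cyp2e1 and Cyp1a2, which oxidise acetaminophen, fell from 77085 ± 25026 to 24303 ± 15945 (log2 fold change -1.86) and from 9962 ± 3689.9 to 1519 ± 1024 (log2 fold change -2.90), and Slc1a4 (1.80) and Avpr1a (0.83) rose. Periportal genes went both ways, 5 of 20 higher, such as Gldc (0.91), and 6 lower, such as Cyp2f2 (-0.63) (6 and 6 adjusted over the list alone; adjusted p = 0.826, adjusted p = 0.95 with an estimated correlation). Secreted proteins and identity factors of the liver held 11 of 25 that fell by small amounts, such as F7 (-0.90) and Ttr (-0.88), and 2 that rose, Apoa4 (3.58) among them (2 and 13 adjusted over the list alone; adjusted p = 0.00645, adjusted p = 0.485 with an estimated correlation). Of 16 male-biased liver genes 8 fell, with 8 adjusted over the list alone (adjusted p = 5.91e-05, adjusted p = 0.357 with an estimated correlation). Examples were the steroid dehydrogenase Hsd3b5 (2764 ± 1049.9 to 111 ± 107, log2 fold change -5.02) and Susd4 (-4.35). Other large falls were those of the uridine phosphorylase Upp2 (8174 ± 2478 to 273 ± 202, log2 fold change -5.08), Keg1 (-4.37), Nxpe2 (-4.15) and Syt1 (-4.12).

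Circadian clock genes of opposite phase moved in opposite directions at 12 h. All 5 genes in the phase of Arntl rose, over all genes and adjusted over the list alone (adjusted p = 8.31e-05, adjusted p = 0.155 with an estimated correlation). The values of Arntl went from 21.9 ± 5.15 to 277 ± 51.9 (log2 fold change 3.61). Of 11 genes in the phase of Dbp and Per 8 fell, and 10 adjusted over the list alone (adjusted p = 6.29e-06, adjusted p = 0.262 with an estimated correlation). The values of Dbp went from 2023 ± 597 to 82.2 ± 56.7 (log2 fold change -4.77). The hours of injection and of killing are not given by the labels.

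Acute phase transcripts rose at the same time. Of 23 acute phase genes 19 rose, with 19 adjusted over the list alone (adjusted p = 6.79e-08, adjusted p = 0.256 with an estimated correlation). Examples were lipocalin Lcn2 (371 ± 291 to 13001 ± 7797, log2 fold change 5.38), the iron regulator Hamp (2.101), Orm2 (3.17) and Serpina3n (2.25). Saa1 and Saa2 (2.75 and 3.74) are near-identical copies, and how their reads divide is uncertain. Of 18 cytokine, chemokine and adhesion genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.60e-04, adjusted p = 0.215 with an estimated correlation), the neutrophil attractant Cxcl2 (4.77) and the monocyte attractant Ccl2 (4.10) among the former and Nfkbia (-0.41) the latter. Neutrophil markers held 9 of 16 that rose (11 adjusted over the list alone; adjusted p = 2.61e-04, adjusted p = 0.283 with an estimated correlation). Examples were S100a8 (3.21), Mmp8 (3.15) and Retnlg (2.76). Monocyte and macrophage markers held 7 of 17 that rose, with the same number adjusted over the list alone (adjusted p = 0.00125, adjusted p = 0.357 with an estimated correlation). The values of Mmp12 went from 4.54 ± 3.37 to 185 ± 18.99 (log2 fold change 5.29). Of 22 interferon-stimulated genes 11 were lower, such as Bst2 (-1.04) and Usp18 (-1.91), and 3 higher, such as Rsad2 (1.67), with the same counts adjusted over the list alone (adjusted p = 0.0025, adjusted p = 0.517 with an estimated correlation). The TGF-beta list had 9 of 18 genes higher, such as Skil (1.40), and 1 lower, Ltbp2 (-1.43), with the same counts adjusted over the list alone (adjusted p = 0.0203, adjusted p = 0.517 with an estimated correlation).

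Nell2 and the cornified-envelope gene Sprr2i had no read in untreated livers and reached 90.0 ± 77.7 and 77.6 ± 37.6 at 12 h, at least 24.65-fold and at least 21.3-fold higher against a floor of 3 reads per library. Reads of Sprr2i are uncertain because of similar Sprr2 copies. Sprr1a rose from 24.5 ± 22.8 to 3869 ± 1101, log2 fold change 7.68 with SE 0.67, adjusted p = 1.18e-08, and Tub from 1.25 ± 1.08 to 254 ± 155 (log2 fold change 6.68). The 12 h library of replicate 4 held 5.61 M reads, and without it 5602 genes differed. The periportal count of lower genes was 2 without 12 h replicate 2, and the liver secreted count 7 without 12 h replicate 3.

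At 24 h the pericentral genes Slc1a2 and Glul were low and Lcn2 and Mmp12 were high. Slc1a2 fell from 2161 ± 651 to 27.7 ± 10.99, log2 fold change -6.25 with SE 0.49, adjusted p = 7.69e-08 (n = 4 and 4), and Glul, the glutamine synthetase of the innermost pericentral hepatocytes (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723), fell from 12494 ± 6129.5 to 619 ± 147, log2 fold change -4.22 with SE 0.37, adjusted p = 1.65e-07. Lcn2 rose from 371 ± 291 to 10791 ± 6385, log2 fold change 5.12 with SE 0.75, adjusted p = 6.70e-05. Mmp12, the macrophage elastase, rose from 4.54 ± 3.37 to 138 ± 43.7, log2 fold change 4.80 with SE 0.50, adjusted p = 1.32e-06.

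Of 25 pericentral genes 20 were lower and 1 higher, with the same counts adjusted over the list alone (adjusted p = 2.52e-13, adjusted p = 0.0891 with an estimated correlation). They included Oat (-2.92, log2), the Wnt targets Lgr5 (-2.71), Axin2 (-1.67) and Sp5 (-3.56), and Cyp2e1 (77085 ± 25026 to 20675 ± 5658, log2 fold change -1.87). Among periportal genes 6 of 20 fell and 1 rose (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.00107, adjusted p = 0.485 with an estimated correlation). Examples were the urea cycle enzymes Ass1 (-1.54) and Asl (-1.32) lower and Ctsc (0.76) higher. The liver secreted and identity list had 11 of 25 lower, such as Cebpa (-0.93) and Serpinc1 (-0.50), and 1 higher, Apoa4 (1.92) (1 and 12 adjusted over the list alone; adjusted p = 1.90e-04, adjusted p = 0.348 with an estimated correlation). Bile acid genes were lower in 12 of 18 cases (1 higher and 14 lower adjusted over the list alone; adjusted p = 1.69e-09, adjusted p = 0.141 with an estimated correlation), and Cyp7a1 went from 2059 ± 719 to 159 ± 89.8 (log2 fold change -3.96). Cyp8b1 (-2.98) fell too. Of 19 fatty acid synthesis genes 11 fell, and 13 adjusted over the list alone (adjusted p = 1.24e-08, adjusted p = 0.17 with an estimated correlation). Of 23 cholesterol synthesis genes 6 fell, and 8 adjusted over the list alone (adjusted p = 2.85e-05, adjusted p = 0.411 with an estimated correlation). For fatty acid oxidation 8 of 25 fell (1 higher and 9 lower adjusted over the list alone; adjusted p = 7.50e-04, adjusted p = 0.448 with an estimated correlation). Examples were Fabp1 (-1.56) and Acot1 (-1.75). Of 13 gluconeogenesis genes 7 fell, and 8 adjusted over the list alone (adjusted p = 5.91e-05, adjusted p = 0.178 with an estimated correlation). Examples were Got1 (-1.51) and Tat (-1.27). Male-biased genes were lower in 10 of 16 cases, and in 14 adjusted over the list alone (adjusted p = 1.25e-07, adjusted p = 0.234 with an estimated correlation). Examples were Hsd3b5 (-5.04) and Elovl3 (-3.77).

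Stress lists still held higher genes at 24 h. The heat shock list had 5 of 16 higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 7.12e-04, adjusted p = 0.357 with an estimated correlation). Examples were Hspb1 (3.09) and Hspa1a (4.35). Immediate early genes were higher in 5 of 18 cases, such as Egr2 (2.92) and Fosl1 (4.25), and lower in 1, Zfp36 (-0.70) (6 and 2 adjusted over the list alone; adjusted p = 0.0305, adjusted p = 0.417 with an estimated correlation). NRF2 targets had 9 of 21 higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p = 7.91e-05, adjusted p = 0.2 with an estimated correlation). Gsta1 went from 11.7 ± 10.6 to 167 ± 43.9 (log2 fold change 4.22, uncertain against Gsta2), Cbr3 (3.24) rose, and Me1 (-1.48) fell. Of 20 unfolded protein response genes 12 rose, and 13 adjusted over the list alone (adjusted p = 7.85e-07, adjusted p = 0.2 with an estimated correlation). Examples were Pdia4 (1.09), Sdf2l1 (1.38) and Calr (0.91). Among p53 targets 7 of 21 were higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.0212, adjusted p = 0.357 with an estimated correlation). Examples were Cdkn1a (3.24) among the higher and Sesn1 (-0.63) among the lower. Of 23 acute phase genes 15 rose, and 20 adjusted over the list alone (adjusted p = 4.40e-10, adjusted p = 0.2 with an estimated correlation). Examples were Orm2 (3.58), Apcs (2.099) and Steap4 (1.66). Of 18 cytokine and adhesion genes 10 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 1.33e-05, adjusted p = 0.178 with an estimated correlation). The values of Ccl2 went from 5.19 ± 6.43 to 64.1 ± 28.9 (log2 fold change 4.20), and Sele (3.31) rose too. Macrophage markers had 6 of 17 higher and 7 adjusted over the list alone (adjusted p = 1.02e-05, adjusted p = 0.214 with an estimated correlation). Neutrophil markers had 4 of 16 higher and 4 adjusted over the list alone (adjusted p = 0.0318, adjusted p = 0.517 with an estimated correlation). TGF-beta genes had 6 of 18 higher, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.0131, adjusted p = 0.485 with an estimated correlation).

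Among clock genes, 4 of 5 in the phase of Arntl rose, and 5 adjusted over the list alone (adjusted p = 0.00251, adjusted p = 0.213 with an estimated correlation). Of 11 genes in the phase of Dbp and Per 8 fell, and 10 adjusted over the list alone (adjusted p = 8.63e-08, adjusted p = 0.2 with an estimated correlation). Examples were Usp2 (-3.86) and Per3 (-2.18). Mmp3 (4.29 ± 5.74 to 74.4 ± 55.7, log2 fold change 4.37) and Sprr1a (5.94) rose, and Rgs16 (-4.28) and Upp2 (-4.79) fell. A fit of the untreated, 24, 48 and 72 h animals alone, all of the high-numbered series, called 3871 genes at 24 h (1836 higher, 2035 lower). Without 24 h replicate 4 the count was 2179, with 4 liver secreted genes lower, 5 cytokine genes higher and 14 cholesterol synthesis genes lower. The acute phase count was 9 without untreated replicate 1, and the TGF-beta count 2 without untreated replicate 4.

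At 36 h transcripts of DNA replication were higher than in untreated livers and those of fatty acid oxidation lower. Mcm6, a subunit of the replicative helicase, rose from 108 ± 33.6 to 661 ± 399, log2 fold change 2.48 with SE 0.36, adjusted p = 1.60e-04 (n = 4 and 4). Gpnmb, a glycoprotein of phagocytic macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), rose from 17.8 ± 8.24 to 402 ± 104, log2 fold change 4.53 with SE 0.48, adjusted p = 4.43e-06. Cyp2b10, an enzyme induced through the receptor CAR, rose from 27.1 ± 18.4 to 494 ± 295, log2 fold change 4.27 with SE 0.67, adjusted p = 3.22e-04. Acot1, an acyl-CoA thioesterase, fell from 249.7 ± 62.7 to 36.3 ± 24.5, log2 fold change -2.94 with SE 0.40, adjusted p = 1.02e-04.

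Of 25 G1/S and replication genes 20 rose, and 21 adjusted over the list alone (adjusted p = 1.97e-17, adjusted p = 0.155 with an estimated correlation). Examples were Uhrf1 (2.97), Mcm5 (2.33), Ccne2 (1.88) and E2f1 (1.52). Of 24 G2/M and mitosis genes 13 rose, and 19 adjusted over the list alone (adjusted p = 1.20e-10, adjusted p = 0.325 with an estimated correlation). Examples were Top2a (35.7 ± 21.98 to 335 ± 355, log2 fold change 2.93), Aurkb (2.56) and Cdk1 (1.96). Without 36 h replicate 2, which had 861 Top2a reads against 96.4 to 231 in the other animals, 2 G2/M and 19 G1/S genes rose. Of 25 fatty acid oxidation genes 19 fell, and 23 adjusted over the list alone (adjusted p = 6.64e-17, adjusted p = 0.124 with an estimated correlation). Examples were the carnitine transferase Cpt1a (-1.29), Vnn1 (-1.50) and Angptl4 (-2.08). Fatty acid synthesis held 3 of 19 higher, Acly (1.27), Pnpla3 (2.77) and Acss2 (0.95), and 2 lower, Fads2 (-0.83) and Dgat2 (-0.57) (4 and 2 adjusted over the list alone; adjusted p = 0.487, adjusted p = 0.879 with an estimated correlation). Of 13 gluconeogenesis genes 3 fell, and 4 adjusted over the list alone (adjusted p = 3.12e-04, adjusted p = 0.209 with an estimated correlation), Pck1 (-1.70) among them. Pericentral genes were lower in 15 of 25 cases and higher in 1, with the same counts adjusted over the list alone (adjusted p = 1.80e-11, adjusted p = 0.115 with an estimated correlation). The values of Glul went from 12494 ± 6129.5 to 666 ± 198 (log2 fold change -4.13). Slc22a3 (-3.29) and Cyp2e1 (-2.06) fell too. The bile acid list had 6 of 18 lower (1 higher and 9 lower adjusted over the list alone; adjusted p = 1.34e-05, adjusted p = 0.213 with an estimated correlation). Examples were Abcb4 (-1.14) and Slc10a1 (-0.98). The liver secreted and identity list had 5 of 25 lower and 1 higher (1 and 6 adjusted over the list alone; adjusted p = 0.0228, adjusted p = 0.558 with an estimated correlation). Of 16 male-biased genes 8 fell, and 11 adjusted over the list alone (adjusted p = 6.44e-07, adjusted p = 0.271 with an estimated correlation). Examples were Susd4 (-2.82) and Cyp4a12b (-3.56, reads uncertain against Cyp4a12a).

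Macrophage markers were higher in 9 of 17 cases, and in 11 adjusted over the list alone (adjusted p = 2.33e-10, adjusted p = 0.141 with an estimated correlation). Examples were Trem2 (3.14), Cd68 (1.89), Lgals3 (2.77) and Cx3cr1 (2.09). Endothelial markers rose in 11 of 19 cases, and in 15 adjusted over the list alone (adjusted p = 4.01e-09, adjusted p = 0.161 with an estimated correlation). Examples were Cdh5 (0.89), Oit3 (1.05) and Kdr (0.86). Of 22 stellate cell and matrix genes 6 rose, and 8 adjusted over the list alone (adjusted p = 1.38e-05, adjusted p = 0.402 with an estimated correlation), Tagln (1.67) and Pdgfrb (1.01) among them, and 2 of 11 Kupffer cell markers, Adgre1 (1.01) and Marco (1.48), with the same number adjusted over the list alone (adjusted p = 0.0368, adjusted p = 0.582 with an estimated correlation). NRF2 targets held 8 of 21 higher, such as G6pdx (1.68), and 1 lower, Ephx1 (-0.59) (10 and 1 adjusted over the list alone; adjusted p = 4.81e-04, adjusted p = 0.234 with an estimated correlation). Acute phase genes had 6 of 23 higher (9 adjusted over the list alone; adjusted p = 0.00237, adjusted p = 0.517 with an estimated correlation), Orm2 (3.33) and Lcn2 (4.03) among them. Of 5 clock genes in the phase of Arntl 3 rose, and 4 adjusted over the list alone (adjusted p = 3.00e-04, adjusted p = 0.169 with an estimated correlation). Of 11 genes in the phase of Dbp and Per 8 fell, and 9 adjusted over the list alone (adjusted p = 8.63e-08, adjusted p = 0.2 with an estimated correlation). Chrna4 (20.5 ± 10.1 to 387 ± 399, log2 fold change 3.41) rose, and Rgs16 (-4.80), Lipg (-3.10) and Ctse (-3.82) fell. No within-series value exists at 36 h. Without untreated replicate 4 the number of differing genes was 1187 (with 2 stellate genes higher and 4 male-biased genes lower), without 36 h replicate 2 it was 1234 (with 3 clock genes lower), and in a fit of the 8 libraries of both groups alone it was 1276.

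At 48 h proliferation, macrophage and matrix transcripts were high. Top2a, the topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), rose from 35.7 ± 21.98 to 599.5 ± 259.7, log2 fold change 4.19 with SE 0.61, adjusted p = 3.28e-05 (n = 4 and 4). Gpnmb rose from 17.8 ± 8.24 to 1496 ± 229, log2 fold change 6.45 with SE 0.48, adjusted p = 7.93e-09, and the macrophage receptor Trem2 from 20.1 ± 14.9 to 404 ± 62.1, log2 fold change 4.70 with SE 0.49, adjusted p = 9.10e-07. Col1a1, a chain of type I collagen, rose from 1583 ± 1265 to 6839.9 ± 2424, log2 fold change 2.58 with SE 0.50, adjusted p = 5.72e-04. Slc1a2 fell from 2161 ± 651 to 9.07 ± 3.04, log2 fold change -7.75 with SE 0.49, adjusted p = 8.54e-10.

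Of 25 G1/S and replication genes 23 rose, and 24 adjusted over the list alone (median log2 fold change 2.19, adjusted p = 6.29e-20, and adjusted p = 0.145 with an estimated correlation). The values of Mcm5 went from 78.9 ± 13.2 to 851 ± 346 (log2 fold change 3.33). Others were Uhrf1 (4.00), Cdc6 (3.18) and Gins2 (3.08). All 24 G2/M and mitosis genes rose, over all genes and adjusted over the list alone (median 3.498, adjusted p = 6.64e-17, and adjusted p = 0.202 with an estimated correlation). Examples were Mki67 (3.74), Aurkb (3.99), Ccnb1 (2.76) and Foxm1 (3.83). The mitotic genes Melk (4.18) and Kif18b (4.02) and the replication factor Chtf18 (4.32) were among the genes with the largest rises. Among p53 targets 10 of 21 were higher, such as Cdkn1a (2.32) and Psrc1 (3.05), and 1 lower, Plk3 (-1.40) (11 and 1 adjusted over the list alone; adjusted p = 0.00131, adjusted p = 0.209 with an estimated correlation).

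Of 17 macrophage markers 15 rose, and 16 adjusted over the list alone (adjusted p = 4.30e-15, adjusted p = 0.0891 with an estimated correlation). Examples were Cd68 (2.75), Lgals3 (3.82), Ccr2 (2.96) and Lyz2 (1.91). Kupffer cell markers rose in 7 of 11 cases, with the same number adjusted over the list alone (adjusted p = 7.23e-05, adjusted p = 0.321 with an estimated correlation). Examples were Marco (2.01) and Cd5l (1.41). Of 18 cytokine and adhesion genes 5 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0137, adjusted p = 0.411 with an estimated correlation), Ccl2 (3.93) and Vcam1 (1.45) among those that rose, and 4 of 16 neutrophil markers rose, with the same number adjusted over the list alone (adjusted p = 0.0735, adjusted p = 0.582 with an estimated correlation), Csf3r (1.58) among them. Endothelial markers were higher in 16 of 19 cases, and in 17 adjusted over the list alone (adjusted p = 3.43e-10, adjusted p = 0.155 with an estimated correlation). Examples were Stab1 (1.41), Fcgr2b (1.05), Wnt2 (1.33) and Rspo3 (0.95). Of 22 stellate cell and matrix genes 20 rose, and 21 adjusted over the list alone (adjusted p = 1.38e-11, adjusted p = 0.202 with an estimated correlation). Examples were Lox (2.89), Col1a2 (2.36), Col3a1 (2.11) and Acta2 (2.00). The TGF-beta list had 7 of 18 higher, with the same number adjusted over the list alone (adjusted p = 3.87e-04, adjusted p = 0.326 with an estimated correlation). Examples were Tgfb1 (1.30) and Tgfb2 (2.31). Lymphocyte and cholangiocyte markers gave other counts. No lymphocyte marker passed the limma test (adjusted p = 0.978, adjusted p = 0.992 with an estimated correlation), with 0 of 20 at an unadjusted p under 0.05 or by edgeR, voom or DESeq2. Of 14 cholangiocyte markers 2 rose, Spp1 (1.41) and Pkhd1 (0.83), while Krt23 (-1.90) fell, the same counts as adjusted over the list alone (adjusted p = 0.561, adjusted p = 0.879 with an estimated correlation).

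Of 25 fatty acid oxidation genes 23 fell, and 24 adjusted over the list alone (median -0.92, adjusted p = 8.43e-17, and adjusted p = 0.124 with an estimated correlation). Examples were Cyp4a10 (1676 ± 628 to 133 ± 101, log2 fold change -3.96), Cpt2 (-1.07), Vnn1 (-1.86) and Acaa1b (-1.59). Of 13 gluconeogenesis genes 9 fell, with the same number adjusted over the list alone (adjusted p = 3.87e-04, adjusted p = 0.213 with an estimated correlation). Examples were Pck1 (-1.30) and G6pc (-1.25). Fatty acid synthesis genes fell in 4 of 19 cases, with the same number adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.517 with an estimated correlation), Me1 (-1.37) among them. Pericentral genes were lower in 14 of 25 cases and higher in 1 (2 higher and 16 lower adjusted over the list alone; adjusted p = 3.95e-08, adjusted p = 0.145 with an estimated correlation). The values of Oat went from 13328 ± 4212 to 1006 ± 102 (log2 fold change -3.67). Glul (-3.78) and Cyp2e1 (-1.81) fell too. Of 18 bile acid genes 7 fell, and 8 adjusted over the list alone (adjusted p = 2.61e-04, adjusted p = 0.291 with an estimated correlation). Examples were Scp2 (-1.24) and Abcb4 (-0.92). In the liver secreted and identity list 3 of 25 fell and 1 rose (0 and 3 adjusted over the list alone; adjusted p = 0.0234, adjusted p = 0.558 with an estimated correlation). Of 16 male-biased genes 5 fell, with the same number adjusted over the list alone (adjusted p = 3.58e-04, adjusted p = 0.411 with an estimated correlation), Ugt2b38 (-2.96) among them. The same was seen for Cyp2c69 and Cyp2c40 (-4.27 and -3.93), whose reads are uncertain within the Cyp2c family. NRF2 targets had 6 of 21 higher and 3 lower, with the same counts adjusted over the list alone (adjusted p = 0.111, adjusted p = 0.582 with an estimated correlation). Examples were G6pdx (1.62), which rose, and Gclm (-0.49), which fell. Cyp21a1, known as an adrenal steroid hydroxylase, rose from 6.45 ± 6.56 to 90.2 ± 37.6 (log2 fold change 4.09). The gluconeogenesis count was 4 without untreated replicate 4, and the bile acid count 4 without 48 h replicate 3. The fit of the high-numbered animals alone called 4660 genes at 48 h (2605 higher, 2055 lower).

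**Figure D3:**
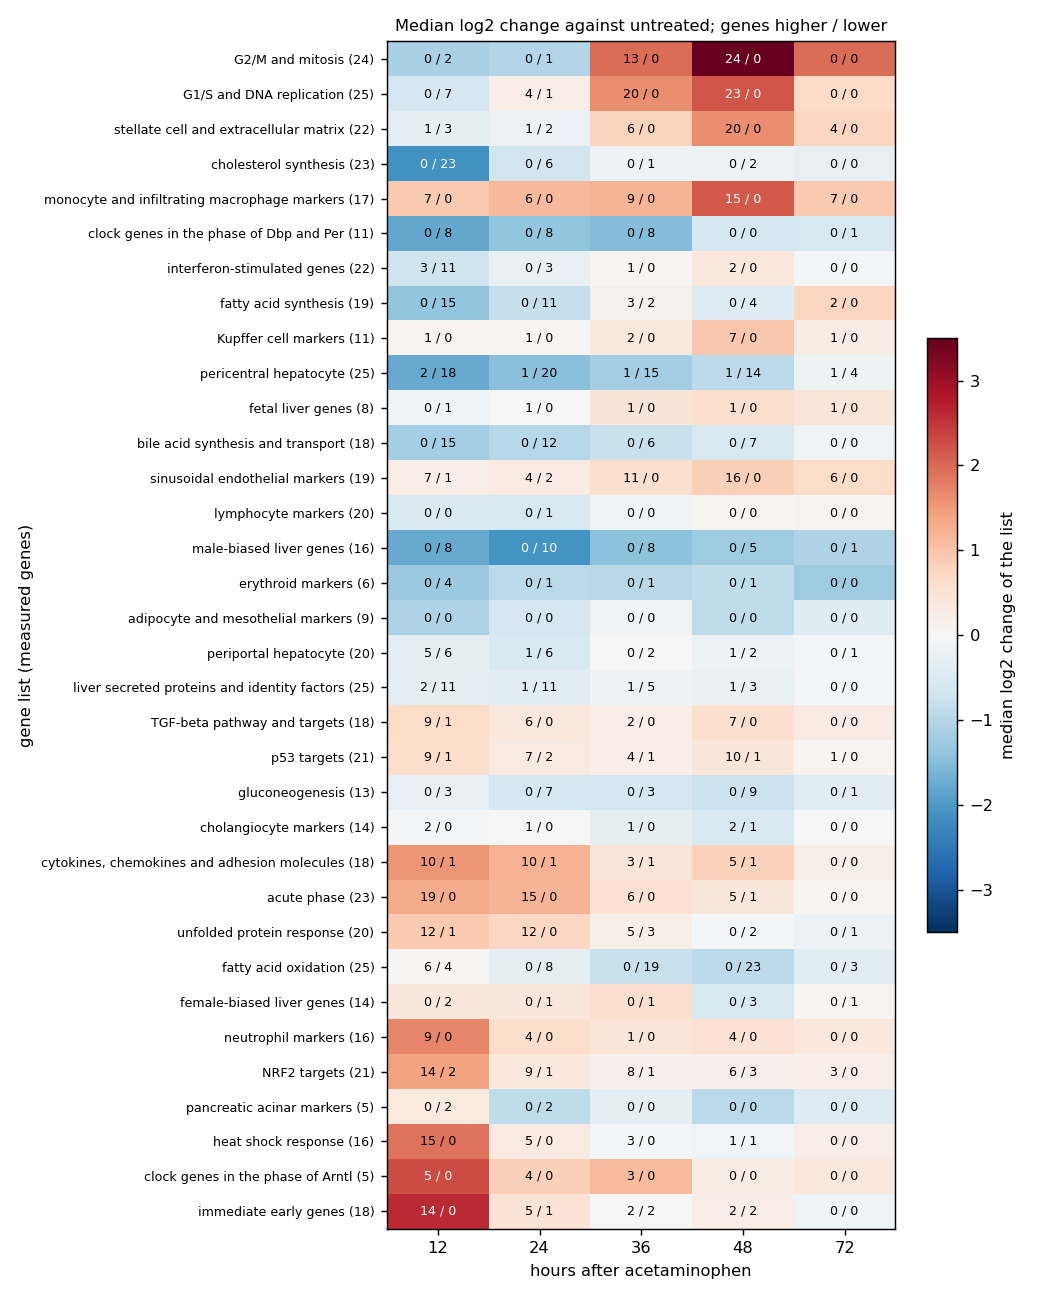
Median log2 change against untreated (colour) of each of the 34 gene lists (vertical axis, measured genes in brackets) at 12, 24, 36, 48 and 72 h (horizontal axis); each field gives the number of genes higher and lower. The cholesterol synthesis field at 12 h reads 0 and 23, and the G2/M field at 48 h reads 24 and 0.

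At 72 h the macrophage genes Gpnmb and Trem2 were high and Slc1a2, Glul and Ctse were low. Gpnmb lay 4.04 above the untreated level on the log2 scale (17.8 ± 8.24 to 368 ± 229.7, SE 0.48, adjusted p = 1.56e-04, n = 4 and 4), and Trem2 rose from 20.1 ± 14.9 to 122 ± 56.7, log2 fold change 2.85 with SE 0.49, adjusted p = 0.00795. Slc1a2 fell from 2161 ± 651 to 42.4 ± 18.7, log2 fold change -5.70 with SE 0.49, adjusted p = 5.27e-07, and Glul from 12494 ± 6129.5 to 3003 ± 927, log2 fold change -1.97 with SE 0.37, adjusted p = 0.0113. Ctse, the protease cathepsin E (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), fell from 87.4 ± 54.0 to 2.01 ± 1.86, log2 fold change -4.65 with SE 0.70, adjusted p = 0.00231.

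Of 17 macrophage markers 7 rose, and 11 adjusted over the list alone (adjusted p = 6.05e-10, adjusted p = 0.141 with an estimated correlation). Examples were Mmp12 (2.36) and Cx3cr1 (1.55). Endothelial markers rose in 6 of 19 cases, and in 18 adjusted over the list alone (adjusted p = 1.48e-14, adjusted p = 0.124 with an estimated correlation). Examples were Oit3 (0.91), Kdr (0.78) and Clec4g (0.72). Of 22 stellate cell and matrix genes 4 rose, and 8 adjusted over the list alone (adjusted p = 3.68e-08, adjusted p = 0.291 with an estimated correlation), Lrat (1.17), Reln (0.99), Col6a3 (1.43) and Dcn (0.87). Kupffer cell markers held 1 of 11 higher, Adgre1 (1.13), and 3 adjusted over the list alone (adjusted p = 0.0115, adjusted p = 0.517 with an estimated correlation). Pericentral genes were lower in 4 of 25 cases, Slc22a3 (-3.26) and Oat (-2.04) besides Slc1a2 and Glul, and higher in 1, Slc1a4 (1.07) (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.00546, adjusted p = 0.391 with an estimated correlation). Cyp2e1 stood at 48493 ± 8141 against 77085 ± 25026 in untreated livers (adjusted p = 0.489). Of 25 fatty acid oxidation genes 3 fell, Vnn1 (-1.27), Cpt1a (-0.89) and Cyp4a10 (-2.32), and 17 adjusted over the list alone (adjusted p = 5.57e-12, adjusted p = 0.158 with an estimated correlation). Fatty acid synthesis had 2 of 19 higher, Acaca (1.04) and Pnpla3 (2.44) (8 higher and 1 lower adjusted over the list alone; adjusted p = 5.09e-05, adjusted p = 0.291 with an estimated correlation). NRF2 targets had 3 of 21 higher, Pgd (0.65), G6pdx (1.09) and Cbr3 (1.70), and 4 adjusted over the list alone (adjusted p = 0.00863, adjusted p = 0.357 with an estimated correlation). Gluconeogenesis had 1 of 13 lower, Pck1 (-1.26), and 2 adjusted over the list alone (adjusted p = 8.31e-05, adjusted p = 0.188 with an estimated correlation). Male-biased genes had 1 of 16 lower, Cyp4a12b (-2.93, uncertain against its copy), with the same number adjusted over the list alone (adjusted p = 3.80e-05, adjusted p = 0.357 with an estimated correlation).

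No G1/S gene and no G2/M gene passed the limma test at 72 h over all genes. Of 25 and 24 such genes, 9 and 21 were higher adjusted over the list alone (adjusted p = 7.01e-07, adjusted p = 0.357 with an estimated correlation for G1/S, and adjusted p = 5.71e-15, and adjusted p = 0.217 with an estimated correlation for G2/M). At an unadjusted p under 0.05, 11 G1/S and 22 G2/M genes were higher. The edgeR test called 0 and 1 of them, voom 0 and 0, and DESeq2 3 and 10. Heat shock genes gave 0 of 16 over all genes and 2 higher adjusted over the list alone (adjusted p = 0.0121, adjusted p = 0.501 with an estimated correlation), with 5 at an unadjusted p under 0.05, 1 by edgeR, 0 by voom and 1 by DESeq2. In the cholesterol synthesis list 0 of 23 passed in limma, edgeR, voom or DESeq2, 3 were lower at an unadjusted p under 0.05, and the median was -0.28 (adjusted p = 0.0305, adjusted p = 0.678 with an estimated correlation). Erythroid markers gave 0 of 6, and 5 lower adjusted over the list alone (adjusted p = 4.75e-05, adjusted p = 0.178 with an estimated correlation), with 5 at an unadjusted p under 0.05 and 0 by edgeR, voom or DESeq2. Of 11 clock genes in the phase of Dbp and Per 1 was lower, Per1 (-1.56), with the same number adjusted over the list alone (adjusted p = 0.00117, adjusted p = 0.411 with an estimated correlation). Further genes that rose at 72 h were Cyp2b10 (3.19), Capn6 (2.50), Ect2 (2.25), Atp2b2 (1.63) and the fetal gene Afp (1.88), and Mup8 fell (-2.52, reads uncertain within the Mup family). The count of 283 genes was 402 in the fit of the high-numbered animals alone (215 higher, 187 lower), 650 by DESeq2, 165 by voom and 15 in a fit of the 8 libraries. It was 115 without untreated replicate 2, 68 without untreated replicate 4, 134 without 72 h replicate 1 and 32 without 72 h replicate 2. The macrophage count was 2 without untreated replicate 4, and the endothelial count 0 in limma without 72 h replicate 2 (14 at an unadjusted p under 0.05).

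The remaining lists held few genes that passed the test. Of 8 fetal liver genes 1 fell at 12 h, Scd2 (-1.17), and 1 rose at each later time, Peg3 (1.15) at 24 h and Afp at 36, 48 and 72 h (1.92, 2.64 and 1.88), with the same counts adjusted over the list alone (adjusted p = 0.577, 0.814, 0.279, 0.246 and 0.0944 for the list). Among 14 female-biased genes Sult2a1 was lower at all 5 times (-2.83 at 12 h, no reads at 72 h), Abcd2 at 12 h (-1.34), and Acot3 and Cyp17a1 at 48 h (-2.88 and -2.19), with the same counts adjusted over the list alone (adjusted p = 0.856, 0.856, 0.849, 0.0866 and 0.972). Cholangiocyte markers that rose were Sox9 (2.62) and Krt23 (1.94) at 12 h, Sox9 at 24 h (2.05) and Pkhd1 at 36 h (0.87), with the same counts adjusted over the list alone (adjusted p = 0.68, 0.552 and 0.833). Of 20 lymphocyte markers only Cd4 at 24 h passed the limma test (-1.65), also adjusted over the list alone (adjusted p = 0.0387 for the list at 24 h, and adjusted p = 0.501 with an estimated correlation). At 12, 36, 48 and 72 h the count was 0, with 3, 1, 0 and 0 lower at an unadjusted p under 0.05 and at most 1 by edgeR, voom or DESeq2. Erythroid markers were lower in 4 of 6 cases at 12 h (adjusted p = 0.0134, adjusted p = 0.385 with an estimated correlation). Examples were Slc4a1 (-1.42) and Alas2 (-1.51) and the haemoglobin genes Hba-a1 and Hbb-bt, whose reads are uncertain between copies. Alas2 alone was lower at 24, 36 and 48 h (-1.31, -0.98 and -1.07, adjusted p = 0.00722, 0.00241 and 0.0225 for the list, and adjusted p = 0.357, 0.291 and 0.411 with an estimated correlation). Counts of 4, 1, 5 and 1 erythroid markers were lower adjusted over the list alone at 12, 24, 36 and 48 h. Of 5 measured pancreatic acinar genes Cela1 and Cela2a were lower at 12 h (-1.71 and -1.80) and 24 h (-1.08 and -1.57), also adjusted over the list alone (adjusted p = 0.297 and 0.0689). The pancreatic list gave 0 at 36, 48 and 72 h in limma, with 1, 1 and 2 at an unadjusted p under 0.05 and at most 1 by edgeR, voom or DESeq2. No adipocyte or mesothelial marker of 9 passed limma at any time, 0 or 1 had an unadjusted p under 0.05, and edgeR, voom or DESeq2 called at most 2 (adjusted p = 0.186, 0.526, 0.627, 0.336 and 0.643).

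Other list and time pairs gave smaller counts. Endothelial markers had 7 higher and 1 lower of 19 at 12 h, such as Lyve1 (2.04), and 4 higher and 2 lower at 24 h, with Wnt2 (-2.16) and Wnt9b (-1.73) the lower ones (7 and 1, and 5 and 2, adjusted over the list alone; adjusted p = 0.112 and 0.109 for the list). Stellate and matrix genes had 1 higher and 3 lower of 22 at 12 h, such as Col1a1 (-1.36), and 1 higher and 2 lower at 24 h, such as Mmp2 (-1.43) (1 higher adjusted over the list alone at both, adjusted p = 0.297 and 0.476). G1/S genes had 7 of 25 lower at 12 h, such as Rrm2 (-1.98), with the same number adjusted over the list alone (adjusted p = 0.0069, adjusted p = 0.621 with an estimated correlation), and 4 higher and 1 lower at 24 h, also adjusted over the list alone (adjusted p = 0.205). G2/M genes had 2 of 24 lower at 12 h, Birc5 (-1.89) and Hmmr (-2.36) (adjusted p = 0.00484, adjusted p = 0.667 with an estimated correlation), and 1 at 24 h, Ccnb2 (-2.32) (adjusted p = 0.00241, adjusted p = 0.64 with an estimated correlation), of which 0 and 1 stood adjusted over the list alone. Kupffer cell markers had 1 of 11 higher at 12 and 24 h, Marco (1.57 and 1.72), also adjusted over the list alone (adjusted p = 0.606 and 0.993). At 36 and 48 h, cholesterol synthesis had 1 and 2 of 23 lower, Tm7sf2 (-0.58) at 36 h among them (0 and 0 adjusted over the list alone, adjusted p = 0.534 and 0.109). Periportal genes had 2 of 20 lower at 36 h, Pck1 and Cyp2f2 (-1.70 and -1.10), 1 higher and 2 lower at 48 h and 1 lower at 72 h (2, 2 and 1 lower adjusted over the list alone, adjusted p = 0.552, 0.328 and 0.276). Acute phase genes had 5 higher and 1 lower of 23 at 48 h, Orm2 (3.07) and Lbp (-0.87) among them, also adjusted over the list alone (adjusted p = 0.0912). Interferon-stimulated genes had 3 of 22 lower at 24 h, 1 higher at 36 h and 2 higher at 48 h, such as Oas2 (1.36), with the same counts adjusted over the list alone (adjusted p = 0.0832, 0.377 and 0.0293 for the list, the last with adjusted p = 0.64 with an estimated correlation). The p53 list had 4 higher and 1 lower of 21 at 36 h and 1 higher at 72 h, Polk (0.61) (6 and 2, and 1, adjusted over the list alone; adjusted p = 0.0618 and 0.129). The unfolded protein response had 5 higher and 3 lower of 20 at 36 h, 2 lower at 48 h and 1 lower at 72 h, Herpud1 (-0.81) (5 and 3, 1 and 1 adjusted over the list alone, adjusted p = 0.547, 0.7 and 0.0593). The TGF-beta list had 2 of 18 higher at 36 h, Tgfb1 (0.68) and Itgav (0.56), also adjusted over the list alone (adjusted p = 0.103). Neutrophil markers had 1 of 16 higher, Clec4d (1.70), and 0 adjusted over the list alone (adjusted p = 0.547). Cytokine genes had 3 higher and 1 lower of 18 at 36 h (6 and 2 adjusted over the list alone; adjusted p = 0.0671). Immediate early genes had 2 higher and 2 lower of 18 at 36 h and 2 higher and 2 lower at 48 h, such as Nr4a1 (-1.97) at 36 h (3 and 3, and 4 and 2, adjusted over the list alone; adjusted p = 0.747 and 0.674). The heat shock list had 3 of 16 higher at 36 h and 1 higher and 1 lower at 48 h, with Cryab higher at both (0.69 and 0.77) and the same counts adjusted over the list alone (adjusted p = 0.855 and 0.591). The median of the heat shock response at 48 h was -0.10, and 0.05 with scaling by total reads. No clock gene of either phase passed limma at 48 h, with 2 of 5 higher and 3 of 11 lower at an unadjusted p under 0.05, and edgeR, voom and DESeq2 called 0 of the former and 1, 1 and 2 of the latter (adjusted p = 0.398 and 0.023, the latter with adjusted p = 0.574 with an estimated correlation). At 72 h the Arntl phase, bile acid, liver secreted, acute phase, cytokine, interferon, TGF-beta, immediate early, neutrophil and cholangiocyte lists had 0 genes past limma and 0 to 5 adjusted over the list alone. Between 0 and 8 of their genes had an unadjusted p under 0.05, and edgeR, voom and DESeq2 called at most 2 in any of them (adjusted p = 0.0547, 0.0663, 0.282, 0.441, 0.638, 0.336, 0.0603, 0.533, 0.407 and 0.836 in that order).

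**Figure D4:**
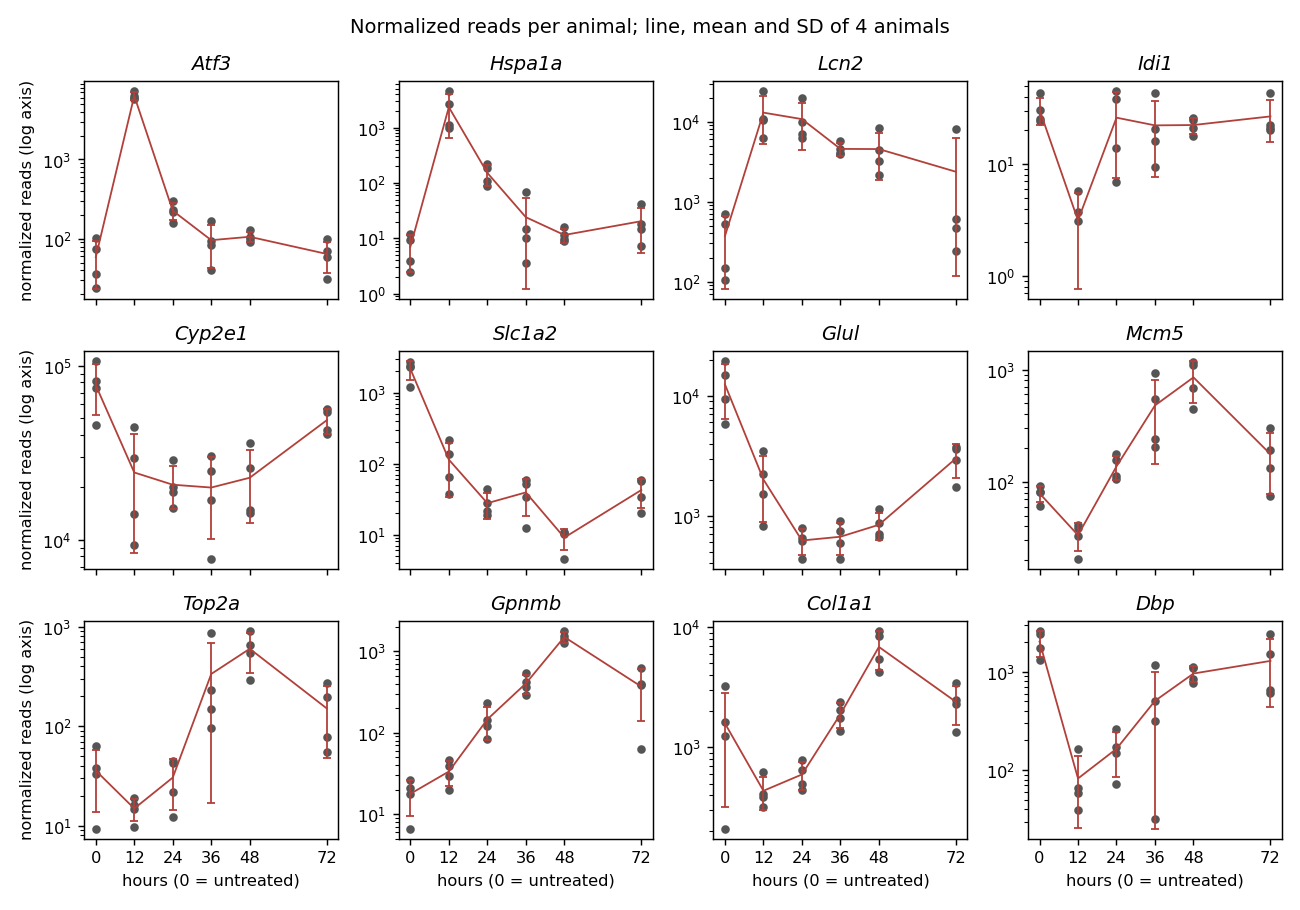
Normalised read counts (log axis) of 12 genes in each animal (points) against hours after acetaminophen, with untreated animals at 0; the line joins the means of 4 animals and the bars are 1 SD, drawn no lower than a small share of the mean. Atf3 is highest at 12 h (6344 ± 677) and Gpnmb at 48 h (1496 ± 229), and Slc1a2 is at 42.4 ± 18.7 at 72 h against 2161 ± 651 in untreated livers.

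Consecutive times were compared to show what differed from one time to the next. From 12 h to 24 h heat shock and immediate early transcripts fell and sterol synthesis transcripts rose. Atf3 fell from 6344 ± 677 to 226 ± 55.6, log2 fold change -4.83 with SE 0.38, adjusted p = 1.65e-08 (n = 4 and 4). Of 16 heat shock genes 14 fell, and 15 adjusted over the list alone (adjusted p = 6.76e-23, adjusted p = 0.0265 with an estimated correlation). Of 18 immediate early genes 12 fell, and 14 adjusted over the list alone (adjusted p = 2.25e-14, adjusted p = 0.0265 with an estimated correlation). Of 23 cholesterol synthesis genes 18 rose, and 20 adjusted over the list alone (adjusted p = 9.61e-17, adjusted p = 0.249 with an estimated correlation), as did Srebf1 (2.27), a regulator of lipid synthesis. Other changes were those of Akr1c6 (2.72), Hsd3b3 (2.47), Aox3 (2.39) and Syt1 (2.67), which rose, and of Maff (-3.83), Fosb (-3.95), Nell2 (-3.75) and Hspa1b (-4.37, uncertain against Hspa1a), which fell. A total of 2188 genes differed (1059 higher, 1129 lower), and 1302 in a fit of the 8 libraries alone. Scaling by total reads shifted the median by 0.111 and gave 1883 higher and 685 lower.

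From 24 h to 36 h cell cycle and fatty acid synthesis transcripts rose. Ckap2l, a spindle protein, rose from 3.85 ± 3.51 to 90.5 ± 109, log2 fold change 3.86 with SE 0.73, adjusted p = 0.00214 (n = 4 and 4). Of 24 G2/M genes 23 rose, and 24 adjusted over the list alone (adjusted p = 1.01e-21, adjusted p = 0.265 with an estimated correlation), Hmmr (3.77) among them. Of 25 G1/S genes 17 rose, and 22 adjusted over the list alone (adjusted p = 1.11e-15, adjusted p = 0.271 with an estimated correlation). Among 19 fatty acid synthesis genes 14 rose, and 16 adjusted over the list alone (adjusted p = 1.68e-13, adjusted p = 0.159 with an estimated correlation). Of 20 unfolded protein response genes 6 fell (1 higher and 16 lower adjusted over the list alone; adjusted p = 5.48e-08, adjusted p = 0.265 with an estimated correlation). Of 25 fatty acid oxidation genes 8 fell, and 11 adjusted over the list alone (adjusted p = 1.46e-07, adjusted p = 0.414 with an estimated correlation). Chrna4 (4.90), Upp2 (3.87) and Iqgap3 (3.75) rose, and Hspb1 (-2.92), Lor (-2.56), Cyp4a10 (-2.48) and Hspa1a (-3.22, uncertain against Hspa1b) fell. The contrast held 1765 genes (931 higher, 834 lower), 728 and 1016 with scaling by total reads, 784 without 24 h replicate 4 and 784 in a fit of the 8 libraries. The fatty acid synthesis count was 7 without 36 h replicate 4, and the fatty acid oxidation count 4 without 24 h replicate 1.

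From 36 h to 48 h few genes differed. Hpgds, a prostaglandin D synthase, rose from 22.4 ± 6.79 to 65.4 ± 7.96, log2 fold change 1.55 with SE 0.29, adjusted p = 0.0179 (n = 4 and 4), and Serpina7, the thyroxine-binding globulin, fell from 283 ± 107 to 61.5 ± 42.0, log2 fold change -2.34 with SE 0.42, adjusted p = 0.0157. Of 17 macrophage markers 4 rose, and 10 adjusted over the list alone (adjusted p = 2.45e-09, adjusted p = 0.214 with an estimated correlation). Of 22 stellate and matrix genes 2 rose, and 10 adjusted over the list alone (adjusted p = 8.33e-09, adjusted p = 0.432 with an estimated correlation). Ubd (2.21), Ltbp2 (1.89), Capn6 (1.87) and Kcnab2 (1.56) rose, and Cyp4a14 (-2.90) and, uncertain within their families, Cyp2a5 (-1.72), Cyp2c69 (-3.96) and Cyp2c40 (-3.13) fell. No G2/M gene passed limma, though 18 of 24 were higher adjusted over the list alone (adjusted p = 2.41e-10, adjusted p = 0.489 with an estimated correlation) and 18 at an unadjusted p under 0.05, with 0 by edgeR, voom or DESeq2. The 183 genes (151 higher, 32 lower) became 522 by DESeq2 (375 and 147), 253 by edgeR with TMM (172 and 81) and 286 by voom. They became 0 without 36 h replicate 1 (limma, 2025 genes at an unadjusted p under 0.05) or 48 h replicate 4 (limma, 1884 genes), 6 without 36 h replicate 4, 9 without 48 h replicate 3, 46 without 48 h replicate 1 and 395 without 36 h replicate 2.

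From 48 h to 72 h DNA replication and macrophage transcripts fell. Timp1, a protease inhibitor, fell from 101 ± 38.8 to 11.4 ± 8.69, log2 fold change -3.21, SE 0.67, adjusted p = 0.00553 (n = 4 and 4). Cyp2a5 (uncertain against Cyp2a4) rose from 620.5 ± 223 to 3799 ± 1632, log2 fold change 2.57, SE 0.40, adjusted p = 5.32e-04. Of 25 G1/S genes 20 fell, and 24 adjusted over the list alone (adjusted p = 6.76e-23, adjusted p = 0.159 with an estimated correlation). Of 24 G2/M genes 5 fell, and 14 adjusted over the list alone (adjusted p = 8.03e-09, adjusted p = 0.496 with an estimated correlation). Of 17 macrophage markers 13 fell, and 14 adjusted over the list alone (adjusted p = 6.58e-13, adjusted p = 0.159 with an estimated correlation), Chil3 (-3.24) among them. Of 22 stellate and matrix genes 7 fell (1 higher and 13 lower adjusted over the list alone; adjusted p = 5.64e-06, adjusted p = 0.507 with an estimated correlation). Of 25 pericentral genes 9 rose, and 13 adjusted over the list alone (adjusted p = 3.76e-09, adjusted p = 0.159 with an estimated correlation), as did 7 of 19 fatty acid synthesis genes, and 15 adjusted over the list alone (adjusted p = 1.79e-12, adjusted p = 0.159 with an estimated correlation). Serpina7 (2.59), Hcn3 (2.35), Cyp2c38 (2.54) and Cyp2c40 (3.29, both uncertain within their family) rose, and Sprr1a (-4.18), Adam8 (-3.31) and Cdh17 (-3.27) fell. The contrast held 1080 genes (337 higher, 743 lower), 1484 among the high-numbered animals alone (510 and 974), and 139 higher and 1029 lower with scaling by total reads, which shifted the median by -0.101. The count was 512 without 48 h replicate 3 (with 0 G2/M genes lower in limma and 9 at an unadjusted p under 0.05), 358 without 48 h replicate 4 (with 3 macrophage genes and 2 stellate genes lower and 5 pericentral genes higher), 491 without 72 h replicate 3 and 541 without 72 h replicate 4.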

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

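Tests of the hour of sampling and of the number series for the clock genes, of fasting, of a few genes taking most of the reads and of the share of hepatocytes were chosen after the results were seen, and the TMM factors in the 48 h scaling test were added after the data were seen. The tests of the shallow library, of scaling by total reads at 48 h and of the other splits were fixed before.

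Single animals apart from the other 3 of their group, by the gap between neighbours over the range, were listed for 296 groups of 4 values, where chance marks about 1 in 20. In the untreated group, replicate 4 had a mean log2 level of liver secreted genes of 14.16 (others 13.89 to 13.93), replicate 2 an immediate early level of 6.028 (6.67 to 6.767) and replicate 1 an adipocyte and mesothelial level of 5.807 (1.964 to 2.601). At 12 h, replicate 4 had 5.614 M reads (14.83 to 16.25), a macrophage level of 6.434 (6.207 to 6.217), an Upp2 value of 574.7 (155.7 to 196.4) and a Susd4 value of 43.83 (6.9 to 13.09). At 24 h, replicate 2 had a stellate and matrix level of 7.04 (7.29 to 7.337), and replicate 1 a cholangiocyte level of 5.872 (4.816 to 4.952) and an erythroid level of 7.321 (8.063 to 8.168). At 36 h, replicate 1 had a pancreatic acinar level of 4.253 (2.615 to 2.886). At 48 h, replicate 1 had a cytokine level of 4.809 (5.2 to 5.252) and a pancreatic acinar level of 3.524 (2.074 to 2.299), replicate 2 an Slc1a2 value of 4.512 (10.35 to 10.76) and an Oat value of 1157 (939.5 to 974.2), and replicate 4 a Trem2 value of 496.0 (363.7 to 385.0). At 72 h, replicate 4 had a bile acid level of 11.67 (12.3 to 12.38) and a neutrophil level of 4.36 (2.355 to 2.549), replicate 3 a cytokine level of 4.544 (4.1 to 4.167) and replicate 2 an endothelial level of 8.407 (7.81 to 7.909). A difference between times was listed once: the G1/S level at 48 h exceeded that at 12 h by 2.739 (log2, exact permutation p = 0.0286).

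The low Dbp and Per phase transcripts at 12, 24 and 36 h could come from the hour of sampling. With the 24 h and 48 h animals taken at 1 hour of the day both would have the same level, but 48 h was higher by 1.22 (log2, exact permutation p = 0.0286). The animal-number series is argued against for 24 h only. The 24 h animals belong to the series of the untreated ones and still differed from them by -1.91 (exact permutation p = 0.0286). For 12 and 36 h the series cannot be told apart from time. Harvest at other hours stays open, because the labels give no hours and the genes in the phase of Arntl were higher at the same times, as a shifted hour would give. So does a change of the clock by the injury.

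All 23 cholesterol synthesis genes were lower at 12 h. A shallow library at 12 h is argued against, since 23 were lower without 12 h replicate 4. A few genes taking most of the reads would lower all others alike in values scaled by total reads. Other genes at or above the lowest untreated level in the list changed by a median of 0.0572 (log2, SD 0.708), against -2.05 for the list, so this is argued against as the whole cause. Fasting of the treated animals may explain part of it and cannot be told apart from the dose: the gluconeogenesis level, which fasting would raise, changed by -0.39 (log2, exact permutation p = 0.114), and the fatty acid oxidation level by 0.54 (exact permutation p = 0.0857). Fasting of the untreated animals is not stated.

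Macrophage, endothelial and stellate markers were higher at 48 h. A lower share of hepatocytes as the only cause would raise the markers of every other cell type alike. The macrophage level instead rose by 2.50 more than the lymphocyte level (log2, exact permutation p = 0.0286). Cholangiocyte markers changed by -0.38 (exact permutation p = 0.429), endothelial by 0.86 and stellate by 1.58 (both exact permutation p = 0.0286). Scaling of the libraries is argued against, since 20 of 22 stellate and matrix genes were higher with the scaling that calls fewer. More of these cells, more transcript per cell, or a lower share of hepatocytes as part of the cause stays open.

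The 8 libraries of each comparison were also split into 4 and 4 in all 35 ways. The real split called the most genes in all 9 comparisons, as 1 of 35. For all but 36 to 48 h (a small lead) this argues against chance without excluding it. The highest of the other splits called 343 genes at 12 h (5776 in the real split), 4 at 24 h (3376), 34 at 36 h (2242), 3 at 48 h (4095) and 2 at 72 h (283). For consecutive times it called 176 from 12 to 24 h (2188), 68 from 24 to 36 h (1765), 180 from 36 to 48 h (183) and 1 from 48 to 72 h (1080). The count from 36 to 48 h also became 0 in limma without 36 h replicate 1 (2025 genes at an unadjusted p under 0.05) or 48 h replicate 4 (1884 genes), so chance is left open there. For the numbers of gene lists chance cannot be excluded: 6, 2, 11, 8 and 16 of the 35 splits gave at least as many lists as the real 22, 24, 17, 19 and 16, and the highest other splits gave 23, 24, 24, 23 and 21.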

How the results depend on the processing

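The edgeR test with TMM, TMM factors in limma and the fit without the 3 libraries of under 10 M reads were chosen after the data were seen. Of 193 alternative gene counts 161 stayed within 1.5 times the reported count and 32 did not, and of 70 list counts 64 did and 6 did not. All 5 mitochondrial shares moved by less than the spread between animals. Of 2578 values of named genes 187 no longer passed, and of 2380 values of single lists 165 no longer passed and 55 passed anew, and none reversed. The numbers of genes from 36 to 48 h and at 72 h depended most on the choice of test. From 36 to 48 h, 183 became 283 by edgeR with relative log expression factors, 286 by voom, 522 by DESeq2, 111 without a filter, 113 with the replicate block, and 0 in limma without the 3 shallow libraries (1398 at an unadjusted p under 0.05). The replicate numbers do not pair the animals: correlations between changes of equal number ran from -0.235 to 0.214. At 72 h, 283 became 165 by voom, 650 by DESeq2, 170 without a filter and 15 with only the 8 libraries. With only the 8 libraries the counts were 1276 at 36 h, 1302 from 12 to 24 h and 784 from 24 to 36 h, and the last was 918 without the shallow libraries. Fewer libraries leave fewer degrees of freedom, and no filter tests more genes; for the other settings the cause was not tested. With an estimated correlation camera called 0 lists at 12, 24, 36, 48 and 72 h (9, 9, 8, 8 and 5 at an unadjusted p under 0.05, and fry 21, 19, 14, 15 and 7). Leaving out 1 library gave 4944 to 5602 genes at 12 h, 2179 to 3175 at 24 h, 1187 to 2328 at 36 h, 2944 to 3880 at 48 h and 32 to 289 at 72 h. For consecutive times it gave 1507 to 2154, 784 to 1691, 0 to 395 and 358 to 988. The lowest at 24 h and from 24 to 36 h came without 24 h replicate 4, at 36 h without untreated replicate 4, at 72 h without 72 h replicate 2, and from 48 to 72 h without 48 h replicate 4. Depth was lowest in 12 h replicate 4 (5.61 M reads), without which 5602 genes were called at 12 h.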

Other observations

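The tests of the Slc1a2 to Glul ratio and of Wnt2, Wnt9b and Rspo3 were chosen after the results were seen. So were the genes named for their course. The animal-number series test was fixed before.

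Some keratin and cornified-envelope genes, picked after their values were seen and not tested as a group, changed in the injured livers. Lor, a cornified-envelope protein, rose from 10.9 ± 5.39 in untreated livers to 600.0 ± 584 at 12 h and stood at 10.8 ± 1.91 at 72 h. Krt5 had 0 reads in untreated livers and reached 38.1 ± 11.7 at 12 h and 42.6 ± 14.6 at 24 h. Krt18, a keratin of hepatocytes and bile ducts, went from 3707 ± 261 to 8376 ± 1660 at 12 h and back to 3292 ± 253 at 72 h. Of bile duct keratins at 12 h Krt23 rose (log2 1.94) and Krt7 and Krt19 did not pass (adjusted p = 0.266 and 0.250). The 36 h livers differed among themselves, with replicates 2 and 4 at -31.3 and -21.4 on the first principal component and replicates 1 and 3 at -2.27 and -3.72.

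Slc1a2 and Glul were still low at 72 h, when 20 of 25 pericentral genes did not pass the test. Loss of the cells that carry both transcripts, with no Glul from other cells, would lower both alike, but the ratio of Slc1a2 to Glul fell by 3.73 (log2, exact permutation p = 0.0286). Cell loss with Glul from other cells stays open. Lower endothelial Wnt signals stay open, as the raised endothelial list could hide them. Wnt2, Wnt9b and Rspo3 averaged 1.08 above untreated at 48 h and 0.46 at 72 h (exact permutation p = 0.0286 and 0.314). The 24 h mean was -1.41 (exact permutation p = 0.0286), and its bearing on Slc1a2 at 72 h was not tested.

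If the animal-number series set the 12 and 36 h livers apart, genes with both means outside the other 4 groups could be many. There were 418, rank 13 among the 15 pairs of groups, against 4928 for 12 and 24 h, which belong to different series. A series effect on single genes at 12 and 36 h cannot be told apart from time.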
